A study of Drosophila simulans and Drosophila sechellia with 24 samples.

How the data were processed

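Gene expression in heads of adult *Drosophila simulans* and *Drosophila sechellia* was measured on spotted arrays of 15552 probes designed on *Drosophila melanogaster* and hybridised with Cy3 and Cy5 at once. The samples form 4 groups, 2 species by 2 treatments: flies given a choice or no choice for a blend of octanoic and hexanoic acid. The labels describe 24 labelled samples on 12 arrays, 6 per group, of which 3 carried each dye, and each of the 6 pairs of groups shared 2 arrays of opposite labelling. Per the labels' protocols, total RNA was amplified to cRNA, cRNA products were pooled, and labelled material was pooled and split again after aminoallyl and after dye incorporation. Nothing in the labels says that the samples of a group came from separate flies or cages, so the p-values measure only the spread between labelled samples, which may be technical.

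The deposited scanner files hold spot intensity on a linear scale, foreground and local background with its SD for 2 channels called Test and Ref, per the file headers, with no normalisation. The 2 files of each array were identical. The software used for spot quantification is not given in the sources used here. The deposited value table holds log2 values, 1 column per labelled sample, made by the authors. Each of its 24 columns was matched to the scanner values: it equals the log2 of 1 background-subtracted channel minus that column's mean, with no loess and no scaling of the spread, so its scale and centring are known. Its column medians for arrays 1 to 12 were -0.26, -0.40, -0.28, -0.28, -0.25, -0.25, -0.30, -0.30, -0.38, -0.37, -0.42 and -0.43 for Cy3, and -0.36, -0.37, -0.37, -0.32, -0.28, -0.38, -0.34, -0.34, -0.28, -0.39, -0.40 and -0.31 for Cy5.

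The files do not say which dye Test holds. The value table takes its Cy3 column from Test on 6 arrays and from Ref on the other 6, in such a way that Test is the sechellia column on all 8 between-species arrays. The spots contradict that reading. The mean log2 Test over Ref ratio of the 4 arrays with sechellia in Cy5 correlated with that of the 4 arrays with sechellia in Cy3 at r = -0.509 over 10797 probes and -0.816 over the brightest 1350, where a fixed species in Test would give a positive value. The part common to both sets correlated with the within-species arrays at r = 0.744 over those bright probes, as a dye effect would. Test was therefore taken as the same dye on every array, and each of the 4 single-species arrays also correlated with that common part, at r = 0.213 to 0.539 over the brightest 1270 genes. That the dye is Cy3 follows from these single-species arrays, whose mean intensity per spot does not depend on it. Over 411 genes past the threshold for the species effect and over 2-fold, the intensity on the sechellia-only arrays minus that on the simulans-only arrays correlated at r = 0.882 with the difference fitted with Test as Cy3, and 376 of them had the same sign, where Cy5 would turn both.

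The background was corrected with normexp and an offset of 50 in limma 3.58.1 (R 4.3.3), each array was normalised by global loess, and the log2 Cy5 over Cy3 ratio was analysed. A probe needed a value on at least 10 arrays and a foreground more than 2 SD above its background in at least 6 of the 24 labelled samples. That filter removed 0 genes, as did the stricter form with 12 of 24, so neither alternative could change a result. Of the probes, 12587 carried 1 gene symbol in the platform annotation, 73 carried several and 2892 were not listed in it. Probes with 1 symbol were used, and for a gene with several probes the one with the highest mean intensity, which gave 10155 genes, 7827 of them with values on all arrays. Of 1192 genes with several probes, the brightest probe passed the threshold for the species effect in 235, and in 168 of these the other probe had the same sign. Both probes passed in only 82, and 79 of those pairs went the same way.

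Differences were fitted per gene with limma's linear model and empirical Bayes moderation over all 12 arrays, with a gene-specific dye term (8 residual degrees of freedom and 2.12 prior degrees of freedom). Where values were missing, the model was solved exactly for that pattern of arrays. p-values were adjusted by Benjamini-Hochberg at 0.05. The contrasts were sechellia minus simulans over both treatments and within each, choice minus no choice within each species, and the interaction, the choice effect in sechellia minus that in simulans. Errors are the model's SE, and group levels are log2 signals per channel after loess and Aquantile scaling, given with their SD. The directions of the genes past the threshold for choice in sechellia were set against equal odds with an exact sign test, chosen after they had been seen. Precision is limited by the number of arrays.

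Before the data were examined, 32 gene lists were fixed, covering chemosensory families, detoxification enzymes, fatty acid metabolism, Osiris genes, immunity, stress, the clock and light sensing, tissue and cell markers, sex and reproduction, cuticle, pigment and ribosomal proteins. The 28 lists with at least 5 genes measured on all arrays were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Members were also adjusted over their list alone, with no correction for the number of lists. The named genes were chosen by a fixed rule: per contrast, the 8 higher and 8 lower genes with the largest change among those past the threshold that bear a name other than a CG or CR number and went the same way on every array pairing the groups, up to 3 members per list with the smallest p, the 5 higher and 5 lower genes with the smallest p where under 5 passed, and Obp56e, Obp57d, Obp57e, Or22a, Or85b, Osi6, Osi7 and Osi8 whatever their p. Obp57d and Osi7 had no tested probe. Other genes named were chosen after their values were seen, and are the remaining members of short lists or of counts.

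The scripts were tested on simulated data built on the 10155 real genes, with 200 genes changed in each contrast. For the species effect, 29.9% of genes changed by 1.5-fold, 59.7% of those changed by 2-fold and 97.0% of those changed by 4-fold were recovered. For the choice effect in sechellia these shares were 2.99%, 29.9% and 78.8%, in simulans 1.49%, 25.4% and 68.2%, and for the interaction 0%, 0% and 42.4%. Alternatives covered the background correction, the within-array normalisation, the dye term, the filter, every probe on its own, the slide series (5 arrays came from 1 run of slide numbers and 7 from another), array weights, the value table, averaged dye swaps, separate-channel fits with and without the number in the sample titles as a block, directly paired arrays alone, and each array left out in turn. Figures were drawn with matplotlib 3.10.9, and statmod 1.5.0, numpy 2.4.6 and pandas 2.3.3 were also used. The probes with no single gene name were left out of the gene tests and are counted in the closing section.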

Results

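RNA abundance was measured in heads of adult *Drosophila simulans* and *Drosophila sechellia* after flies had been given a choice or no choice for a blend of octanoic and hexanoic acid, acids of the noni fruit on which sechellia feeds. The 4 groups, simulans no choice, simulans choice, sechellia no choice and sechellia choice, held 6 labelled samples each, 3 in Cy3 and 3 in Cy5, on 12 two-colour arrays. Each array gave values for 14064 to 15181 spots. The median signal net of background per array ran from 176 to 3469 in the channel called Test and from 355 to 2119 in the channel called Ref. Both low ends were on array 2, 1 of the 2 arrays that paired the sechellia groups, and the next lowest were 929 and 806 on array 11. Of the spots, 91.2% to 100% lay more than 2 SD above their local background, which does not show that their genes were expressed. On array 3 even the 5th percentile of the net Test signal was 2444, against a median of 2957 and a median background of 509. Differences are log2 ratios with the SE of a limma fit to all 12 arrays and Benjamini-Hochberg adjusted p-values over 10155 genes.

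The comparison of the species over both treatments asks how heads of the noni specialist and of its generalist relative differ. The antimicrobial peptide Defensin (Def, NCBI gene 36047) was higher in sechellia by 4.23 ± 0.10 on the log2 scale, an 18.7-fold difference (adjusted p = 8.87e-09), with mean log2 levels of 14.8 and 14.2 in the sechellia groups and 10.2 and 10.5 in the simulans groups. Tektin-C (38653), of a family of ciliary proteins, was higher by 5.18 ± 0.18 (adjusted p = 2.15e-07). The odorant-binding proteins Obp56e (37267) and Obp18a (32897) were lower, Obp56e by 14.2-fold (-3.83 ± 0.10, adjusted p = 1.35e-08) and Obp18a with a log2 difference of -4.00 ± 0.45. The cytochrome P450 Cyp6a20 (36664) was lower too (-3.94 ± 0.26), as were PPO2 (35910) and PPO1 (37044), the prophenoloxidases of melanin formation in the blood (-3.47 ± 0.23 and -3.41 ± 0.39). The sizes for genes that are dim in 1 species depend on the background correction. Tektin-C lay at 6.55 and 6.65 in the simulans groups, where 1% of all levels lie under 6.82, and its difference ran from 1.85 without correction to 6.74 with an offset of 0. That of Obp18a ran from -1.98 to -4.42, of Cyp6a20 from -1.70 to -4.51, of PPO2 from -2.02 to -3.63 and of PPO1 from -1.42 to -3.96, against 3.47 to 4.28 for Def and -3.20 to -3.86 for Obp56e. In all, 1756 of 10155 genes differed, 825 higher and 931 lower in sechellia. Of these, 430 differed by more than 2-fold, 224 higher and 206 lower, and 81 by more than 4-fold, 38 higher and 43 lower. All are differences in hybridisation to probes designed on *D. melanogaster*, from which abundance was not separated. Among genes with several probes, the brightest probe passed in 235. The other probe had the same sign in 168 of these and passed too in 82. Without background correction 1056 of the 1756 differences were smaller by more than 1.5 times, 1753 kept their sign and 1363 stayed past the threshold. With subtraction these numbers were 728, 1755 and 1609, and with an offset of 0 they were 0, 1756 and 1664. In the value table the balance was 509 higher and 1110 lower. Here and below its columns were reassigned to the dyes as read above, unless its own columns are named.

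CG32523 (-4.58 ± 0.21) and CG11426 (-3.88 ± 0.10), taken up under choice, were also among the genes with the largest differences. Among genes with a name other than a CG number, the next were pdgy (log2 difference 3.17 ± 0.09) and Acsx3 (2.87 ± 0.12), both of the acyl-CoA synthetase family, the pupal cuticle protein gene Pcp (3.24 ± 0.40), Alg14 of protein glycosylation (3.15 ± 0.16), smp-30 (2.87 ± 0.12) and ScsbetaG, a subunit of succinyl-CoA synthetase (2.75 ± 0.17). On the lower side were simj (-3.71 ± 0.37) and the cytochrome P450s Cyp313a1 (-3.63 ± 0.24) and Cyp6t1 (-3.34 ± 0.26). Between no background correction and an offset of 0, simj ran from -1.51 to -4.43, Cyp313a1 from -1.60 to -4.03, Cyp6t1 from -1.02 to -4.17, CG32523 from -2.74 to -4.93, Pcp from 1.07 to 4.11 and ScsbetaG from 1.32 to 2.92. The ranges were narrower for pdgy (2.44 to 3.22), Acsx3 (2.07 to 2.92), Alg14 (2.15 to 3.22), smp-30 (2.35 to 2.89) and CG11426 (-3.16 to -3.92).

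**Figure D1:**
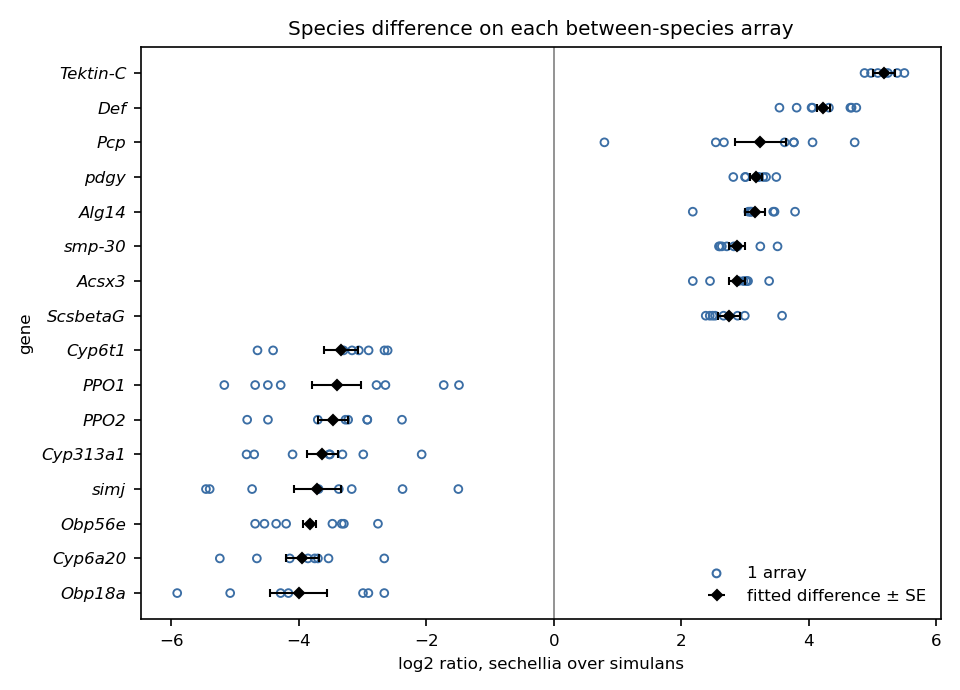
Log2 ratio of sechellia over simulans on each between-species array (open circles) and the fitted difference with its SE (diamonds) for the 8 named genes most higher and the 8 most lower in sechellia. Genes were drawn on condition that all arrays shared a sign, and the fitted differences run from -4.00 for Obp18a to 5.18 for Tektin-C.

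Among odorant-binding proteins, 4 of 34 measured genes were higher in sechellia and 7 lower, with the same numbers when adjusted over the list alone. Obp99b (1.94 ± 0.11) and Obp44a (1.27) were among the higher ones, with Obp8a (0.53) and Obp83ef (0.68). The lower ones were Obp56e, Obp18a, Obp83cd (-1.86), Obp56h (-0.98), Obp56d (-0.74), Obp56a (-0.69) and Obp28a (-0.62). Of 47 odorant receptors, Or33b was higher (0.67) and Or69a lower (-0.56), and only Or33b stayed past the threshold over the list alone. Or33b is among the dimmest genes, had 1 sign on 5 of 7 arrays, and lay at 0.06 without background correction and 0.04 with subtraction (adjusted p = 0.679 and 0.79). Of 36 ionotropic receptors, Ir94e was higher (0.51) and Ir41a lower (-0.72), and neither passed over the list alone or kept its call without correction (0.0071 and -0.09) or with subtraction (0.09 and -0.22). None of 24 gustatory receptors passed in either way. Among 16 other antennal proteins CheA75a was higher (0.74), also over the list alone. Of the measured genes fixed in advance from earlier work on noni feeding, Obp56e passed and 5 did not: Or22a (-0.34 ± 0.13, adjusted p = 0.108), Obp57e (-0.18 ± 0.23, adjusted p = 0.678), Or85b (0.05 ± 0.21, adjusted p = 0.917), Osi8 (0.58 ± 0.58, adjusted p = 0.574) and Osi6 (-0.37 ± 0.41, adjusted p = 0.609). None of 15 Osiris genes passed, over all genes or over the list alone. The Osiris and receptor lists were dim. Their median log2 intensities were 8.66 (Osiris), 8.86 (ionotropic), 8.98 (odorant) and 9.14 (gustatory), against 9.44 over all genes. Only 4 of the 15 Osiris genes had values on all arrays. The lowest group levels were 7.35 for Osi6, 8.31 for Osi8, 8.44 for Obp57e, 8.74 for Or85b and 8.99 for Or22a. Dim genes that did not pass are thus not shown to be equal in the species.

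Detoxification families held many genes that differed, in both directions. Of 73 cytochrome P450s, 10 were higher in sechellia and 17 lower (12 and 18 over the list alone), with Cyp309a2 (2.63 ± 0.09), Cyp4s3 (2.47), Cyp6a8 (2.15) and Cyp12e1 (1.85) on the higher side and Cyp6a20, Cyp313a1, Cyp6t1 and Cyp6d2 (-1.98) on the lower. Of 31 glutathione S-transferases, 4 were higher and 11 lower, as over the list alone, led by GstS1 (1.72) and GstE7 (1.20) against GstE6 (-2.83), GstE1 (-1.78), GstD9 (-1.71) and GstE9 (-1.59). Of 29 UDP-glycosyltransferases, 2 were higher and 5 lower, as over the list alone, among them Ugt49C1 (0.63), Ugt303A1 (-1.56), Ugt317A1 (-1.34), Ugt35B1 (-1.20) and Ugt302C1 (-0.83). Of 12 carboxylesterases, 3 were higher and 4 lower, as over the list alone. The esterase Est-Q (40381) was lower (-3.30 ± 0.14, adjusted p = 2.15e-07), alpha-Est2 (-2.65) and alpha-Est10 (-1.63) were lower, and alpha-Est3 (1.75) higher. Without background correction many of these were far smaller, as Est-Q (-1.71), alpha-Est2 (-1.63), GstE6 (-1.34), Cyp4s3 (1.12), Cyp6a8 (0.98), Cyp6d2 (-0.50) and Ugt303A1 (-0.37), against 1.90 for Cyp309a2 and 1.59 for GstS1.

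Fatty acid oxidation genes were shifted towards sechellia: 7 of 11 were higher and 1 lower (8 and 1 over the list alone), with a median log2 difference of 0.54. The acyl-CoA dehydrogenase family member Arc42 (42364) was 5.08-fold higher (2.34 ± 0.11), and scu (1.22), Acsl (1.12), Echs1 (0.83), yip2 (0.57), CPT2 (0.54) and Acox57D-p (0.50) were also higher, while Acox57D-d was lower (-0.62). The camera test gave adjusted p = 1.61e-04 for the list and adjusted p = 0.355 with an estimated correlation. The median was 0.64 and 0.68 on the slides of either series. Of 11 genes of fatty acid synthesis, desaturation and elongation, 2 were higher and 2 lower (3 and 2 over the list alone), among them ACC (0.96), Desat1 (0.44), bond (-1.01) and ifc (-0.40). Of 7 lipase and lipid droplet genes, bmm (-0.35) and Lip1 (-0.76) were lower and 0 higher, as over the list alone.

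Antimicrobial peptides and recognition proteins were also shifted towards sechellia, with 7 of 21 higher and 4 lower (11 and 4 over the list alone) and a median of 0.32. Besides Def, the higher members were DptB (2.38), BomBc3 (1.98), PGRP-SB1 (1.77 ± 0.08), IM33 (1.20), Mtk (0.38) and BomBc2 (0.32), and the lower ones Listericin (-1.26), BomT3 (-1.03), Drsl6 (-0.93) and PGRP-LE (-0.45). The camera test gave adjusted p = 0.0367, and adjusted p = 0.355 with an estimated correlation. The call ended without any 1 of 5 arrays, at up to adjusted p = 0.0692, with the slide series as a block (adjusted p = 0.0535) and with print-tip loess (adjusted p = 0.0567). The median was 0.27 in series A, the 7 arrays of 1 run of slides, and 0.40 in series B, the other 5.

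Cytosolic ribosomal protein genes were shifted towards simulans, with 8 of 30 lower in sechellia and 0 higher (11 lower and 1 higher over the list alone) and a median of -0.22. RpL37A (-1.28 ± 0.14), RpS29 (-1.05) and RpL36A (-0.82) were the leading members. The camera test gave adjusted p = 9.09e-05, and adjusted p = 0.164 with an estimated correlation. The median was -0.17 in series A and -0.27 in series B. Of 62 mitochondrial ribosomal proteins, 10 were higher and 3 lower (11 and 3 over the list alone), among them mRpL51 (0.79), mRpL16 (0.61) and mRpL52 (-0.74).

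Among neural lists, 1 of 16 neuronal genes was higher, Vmat (0.76), the vesicular monoamine transporter, and 4 lower: the calcium sensor gene Frq1 (-1.03), Syn (-0.85), elav (-0.58) and the GABA receptor gene Rdl (-0.52), with 1 higher and 8 lower over the list alone and a median of -0.44. Of 10 glial genes, Gs2 was lower (-0.57). Of 11 clock genes, tim (0.62) and cry (0.30) were higher and the neuropeptide gene Pdf (-1.41 ± 0.18), Pdp1 (-0.58) and cyc (-0.29) lower. Of 17 phototransduction genes, 2 were higher, inaC (0.63) and santa-maria (0.41), and 4 lower (2 and 5 over the list alone), among them trp (-0.68), ninaB (-0.59) and rdgB (-0.52). Of 15 genes of catecholamine and pigment metabolism, 3 were higher and 4 lower (3 and 5 over the list alone), with ry at 1.13, the eye pigment gene cn at -2.30 ± 0.30 and Ddc, the dopa decarboxylase, at -0.82 (cn at -0.86 and Pdf at -0.89 without background correction). The glial and clock numbers were the same over the list alone.

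Of 13 fat body genes, 2 were higher and 5 lower (2 and 6 over the list alone): the transferrin gene Tsf1 (1.64 ± 0.09) and tobi (1.45) against Fbp2 (-2.04) and sxe2 (-0.82) among others. Of 82 cuticle genes, 6 were higher and 1 lower, as over the list alone, with Pcp, Cpr50Cb (1.92), Cpr100A (1.12) and Cpr47Ee (0.99) against Ccp84Ab (-0.67). Without background correction Fbp2 was -0.53, tobi 0.34, Cpr50Cb 0.56 and Cpr100A 0.38, against 1.42 for Tsf1. Of 30 gut genes, Mal-B2 was higher (1.09), and Mal-A4 (-0.81) and LysX (-0.73) lower, as over the list alone. Of 15 muscle genes, Mf (-0.88) and Tm2 (-0.39) were lower, and of 13 heat shock genes Hsc70-1 (-1.06) and Hsc70-5 (-0.79), in both lists with 0 higher and the same numbers over the list alone. Among markers of sex and reproduction, the yolk protein gene Yp3 was lower (-0.83 ± 0.15), the only one of 11 yolk and eggshell genes and of 4 female markers over all genes, with 2 female markers lower over the list alone. Of 22 germline genes BicD was lower (-0.57), the 1 measured male marker was lower, sxe2 again, and none of 22 male reproductive genes passed. Neither Turandot stress gene passed, TotB at -0.30 and TotF at -0.00. Camera called 3 of 28 lists, those of fatty acid oxidation, antimicrobial proteins and cytosolic ribosomal proteins. In 8 of the others, odorant-binding proteins and carboxylesterases among them, the median, the mean and the test did not share a direction.

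**Figure D2:**
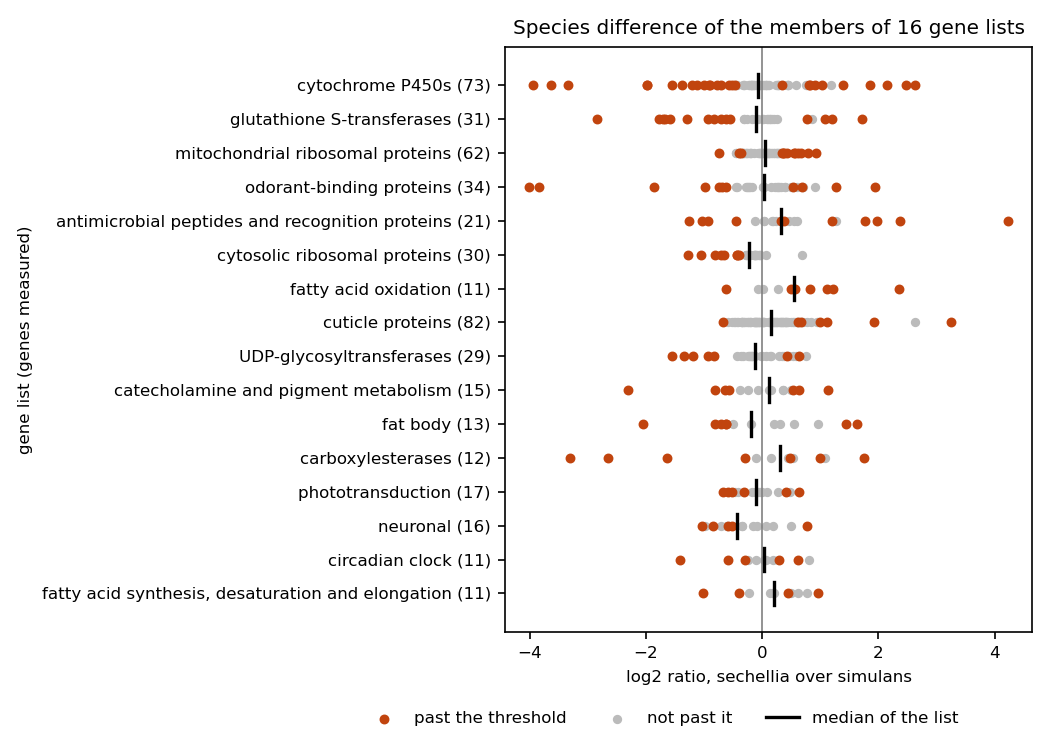
Log2 ratio of sechellia over simulans of each measured member of 16 gene lists, with members past the threshold in orange and the list's median as a bar. The median of fatty acid oxidation lies at 0.54 and that of cytosolic ribosomal proteins at -0.22, while detoxification families spread to both sides.

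Between the slide series the species differences correlated at r = 0.57 over 9571 genes, 0.784 over the brighter 5009 and 0.950 over the brightest 1268. The limma count was 333 in series A alone and 0 in series B alone (1362 at unadjusted p), 21 on directly paired arrays and 649 with averaged dye swaps. These settings, here and below, leave few residual degrees of freedom, so a low count does not show that a difference fails to repeat. The arrays hold no measure of how well transcripts of either species match the *D. melanogaster* probes, so hybridisation and abundance were not separated. Without background correction the calls of Obp8a, Or69a, CPT2, Acox57D-p, ifc, Lip1, bmm, IM33, tim, Mal-A4, LysX and Ccp84Ab also ended, and those of Acox57D-p, Lip1, IM33, tim, LysX and Ccp84Ab with subtraction too. With an offset of 0 those of Ir94e, Lip1, IM33, cry and elav ended.

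Within treatments, 918 genes differed between the species under no choice, 459 in either direction, and 1018 under choice, 469 higher and 549 lower. In the value table these were 334 higher and 383 lower under no choice and 207 higher and 872 lower under choice. The count under no choice was 578 without array 8. Under choice it was 451 without array 3, 460 without array 10 and 1969 with array weights. Def differed by 4.67 and 3.78, Obp56e by -4.40 and -3.26, Tektin-C by 5.18 and 5.18, Cyp6a20 by -4.04 and -3.85, PPO2 by -2.90 and -4.04 and pdgy by 2.93 and 3.41 under no choice and choice. The r between slide series was 0.255 and 0.430 over the same 9571 genes and 0.919 and 0.917 over the brightest 1268. In series A alone limma gave 0 genes under no choice (1233 at unadjusted p) and 22 under choice. In series B alone it gave 0 for both (1492 and 759 at unadjusted p).

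The comparison of choice with no choice within sechellia asks which genes in the head respond to the choice treatment in the specialist. The C-type lectin gene lectin-28C (53542) rose by 1.91 ± 0.17 on the log2 scale (adjusted p = 0.00392), CG32523 (318071) rose by 2.68 ± 0.29 (adjusted p = 0.0103), CG11426 (40471) rose 2.43-fold (1.28 ± 0.14), Obp56e rose 2.30-fold (1.20 ± 0.15, adjusted p = 0.0128) and CG9360 (32128) rose 2.00-fold (0.998 ± 0.13). The genes hll (34822), CG3999 (41253), Had1 (32592), CG9119 (38124) and Nmdmc (47895), the last an enzyme gene of folate metabolism, fell by 3.02-fold, 2.44-fold, 2.16-fold, 2.09-fold and 2.03-fold (-1.60 ± 0.19, -1.28 ± 0.15, -1.11 ± 0.16, -1.06 ± 0.13 and -1.02 ± 0.14). The size of the rise of dim genes depended on the background correction: CG32523, at 6.98 under no choice, ran from 1.11 without correction, where its call ended (adjusted p = 0.0616), to 3.95 with an offset of 0, and lectin-28C from 0.73 to 2.39. The call of Had1, a bright gene, ended with an offset of 0 (-1.11, adjusted p = 0.0512). These 10 of 10155 genes passed, 5 up and 5 down, against 727 at unadjusted p. The even balance depended on the setting. It was 7 up and 23 down without background correction, 8 and 28 with subtraction, 7 and 18 with array weights, 24 and 291 in the value table, and 12 and 11 with print-tip loess. All 10 also differed between the species, and for 8 of them the difference from simulans was smaller under choice, where chance gives 5 (p = 0.109, exact 2-sided sign test): CG32523 went from -6.03 to -3.14, hll from 2.10 to 0.42 and Nmdmc from 1.29 to -0.04. For the other 2, lectin-28C went from -0.40 to 2.00 and CG3999 from 0.03 to -1.14.

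Antimicrobial peptides and recognition proteins were shifted down with choice in sechellia, with a median of -0.33. None of the 21 passed over all genes, while 5 fell over the list alone: Drsl5 (-1.08), AttD (-1.01), Def (-0.83), Drs (-0.83) and BomBc2 (-0.51). The camera test gave adjusted p = 6.93e-05, and adjusted p = 0.0657 with an estimated correlation. The median was -0.19 in series A and -0.73 in series B. Over their own lists alone, the lipid droplet genes Lsd-1 (0.57) and Lsd-2 (0.54), the odorant-binding protein gene Obp99a (0.82), Or33b (1.40), apolpp (0.43), fit (0.46) and the histamine recycling gene t (0.50) also rose. The lipase genes bmm (-0.37) and Lip1 (-0.95), Tsf1 (-0.61), CheA75a (-0.58), Mal-B2 (-0.87) and sxe2 (-0.32) fell. None of these risen or fallen genes passed over all genes, and the adjustment over a list alone does not allow for the number of lists. Or33b is among the dimmest genes and was 0.15 without background correction and 0.22 with subtraction (adjusted p = 0.729 and 0.699 over the list alone). Lsd-2, bmm and Lip1 did not pass over the list alone without background correction either, nor Lip1 with subtraction. Camera called the antimicrobial list alone of 28.

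The 10-gene count ended without array 7, 1 of the pair that held both sechellia groups (0 genes in limma, 516 at unadjusted p). It was 1 to 4 without array 2, 3, 10 or 11 and 4 with the slide series as a block. In the value table with reassigned columns it was 315, and with the table's own columns 0 (1226 at unadjusted p). On arrays 3, 6 and 7, which held the Cy3 sechellia choice samples, the Test channel had its narrowest range of values. Over all genes the choice differences of the slide series correlated at r = -0.247, and over the brightest 1268 at 0.274. In both species, the array that pairs the treatments carried choice in Cy3 in series A and in Cy5 in series B. Slide series and labelling therefore cannot be told apart here. Either series alone, with few residual degrees of freedom, gave 0 genes in limma (723 and 410 at unadjusted p).

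The same comparison within simulans asks which genes respond in the generalist. Ag5r (44631), which encodes a secreted protein of the antigen 5 family, rose by 3.87 ± 0.40 on the log2 scale with choice (adjusted p = 0.018). Its rise ran from 1.61 without background correction to 4.41 with an offset of 0. It was the only gene of 10155 past the threshold, against 805 at unadjusted p. The nearest others were PGRP-SB1 (0.81, adjusted p = 0.21), Tsf1 (0.68), Cdc5 (0.83) and whe (3.5 ± 0.69) on the higher side and Or67d (-2.22), Charon (-0.83), Arl8 (-0.75), TTLL5 (-0.88) and RhoGAP92B (-0.75) on the lower. Without background correction these were, in that order, 0.65, 0.45, 0.45, 1.56, -0.88, -0.36, -0.17, -0.32 and -0.03. Over their lists alone PGRP-SB1 and Tsf1 rose, and Or67d and the muscle gene bt (-0.57) fell, bt not with an offset of 0 (adjusted p = 0.0557 over the list alone), and no list passed camera. The call of Ag5r ended with normexp at an offset of 0 (adjusted p = 0.237), with array weights (adjusted p = 0.0796), with the slide series as a block (adjusted p = 0.065), with averaged dye swaps, on the directly paired arrays and without array 1, 4, 5, 9, 10 or 11 (adjusted p from 0.0714 to 0.102). The r between slide series was 0.176 over all genes and 0.220 over the brightest 1268, and either series alone gave 0 genes in limma (896 and 647 at unadjusted p).

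**Figure D3:**
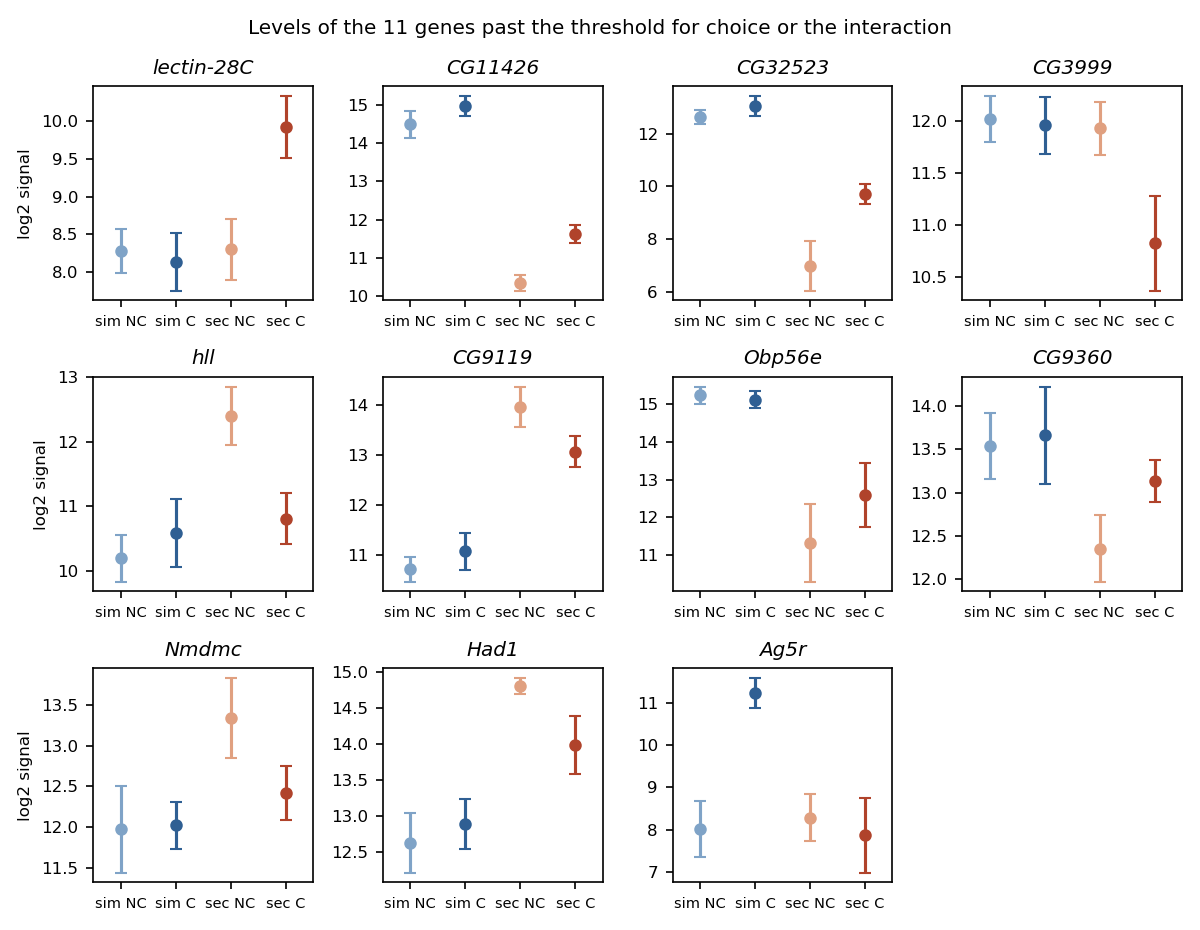
Mean log2 signal with SD (n = 6 labelled samples per group) in simulans (sim) and sechellia (sec) under no choice (NC) and choice (C) for the 11 genes past the threshold for choice in either species or for the interaction. The mean of Ag5r stands apart in simulans under choice and that of lectin-28C in sechellia under choice.

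The interaction asks whether the species respond differently to choice. The choice effect was larger in sechellia than in simulans for lectin-28C (2.40 ± 0.24, adjusted p = 0.0119) and lower in sechellia for Ag5r (-4.39 ± 0.56, adjusted p = 0.0443) and CG9119 (-1.47 ± 0.18, adjusted p = 0.0443). These 3 of 10155 genes passed, against 679 at unadjusted p. Under the background settings lectin-28C ran from 0.83 without correction to 2.95 with an offset of 0, Ag5r from -1.66 to -5.05 and CG9119 from -1.27 to -1.49. Each call ended under some of them: that of lectin-28C without correction (adjusted p = 0.145) and with subtraction (adjusted p = 0.0581), and those of Ag5r and CG9119 with an offset of 0 (adjusted p = 0.134 and 0.0699). The nearest others bearing a name, none of them past the threshold, were Tsf1 (-1.29, adjusted p = 0.0548), Nmdmc (-1.33, adjusted p = 0.0633), Cdc5 (-1.50), Prx6c (-1.44), Obp56e (1.13, adjusted p = 0.159), Obp99a (0.94), Pdh (1.05) and Tmlh (0.85). Cdc5 was -0.77 without background correction. Antimicrobial peptides and recognition proteins were shifted down in sechellia relative to simulans (median -0.29), with 0 of 21 past the threshold over all genes and 7 lower over the list alone, among them AttD (-1.64), Drs (-1.42), Def (-0.89) and PGRP-SB1 (-0.84). The camera test gave adjusted p = 8.87e-04, and adjusted p = 0.133 with an estimated correlation, and without array 1 the call ended (adjusted p = 0.104). The median was -0.09 in series A and -0.63 in series B. Of the odorant-binding proteins, Obp99a and Obp56e were higher and Obp44a (-0.79) and Obp47a (-1.04) lower over the list alone. In other lists, again over the list alone, Acox57D-p, fit (0.62) and t (0.68) were higher and Tsf1 and Mal-B2 (-1.18) lower. Without background correction Obp47a (-0.21), Acox57D-p (0.31) and Mal-B2 (-0.69) did not pass over the list alone, nor did Obp47a and Acox57D-p with subtraction or t with an offset of 0, and AttD was -0.66. The 3-gene count was 0 without array 3 or array 7 (576 and 537 at unadjusted p), 1 without any of 9 others, 0 with median centring (588 at unadjusted p) and up to 17 with other settings. The r between slide series was 0.007 over all genes and 0.495 over the brightest 1268, and either series alone gave 0 genes in limma (762 and 281 at unadjusted p).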

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

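The tests of explanations in this part were chosen only after the results they measure had been seen, and the splits of the samples were counted after the gene counts were known, while the interaction test and the gene list test were planned.

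In 7 of 127 groups of arrays or samples tested for a single distant value, 1 value stood apart by Dixon's test, against 6.35 expected, since chance gives about 1 in 20. On array 8 the ratio of the species for Arc42 was 2.94, against 2.17 to 2.42 on the others. On array 6 that for Alg14 was 2.18, against 3.05 to 3.78. On array 3 that for cn was -4.52, against -2.24 to -1.31. The log2 level of lectin-28C in the Cy5 sechellia no choice sample of array 1 was 7.50, against 8.33 to 8.66 in its group. That of CG32523 in the Cy5 simulans no choice sample of array 8 was 12.1, against 12.6 to 12.9. That of hll in the Cy3 simulans no choice sample of array 5 was 9.53, against 10.2 to 10.5. That of Ag5r in the Cy3 sechellia choice sample of array 3 was 6.16, against 7.92 to 8.67.

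The choice effect differed between the species in limma's interaction test for lectin-28C (2.40), Ag5r (-4.39) and CG9119 (-1.47), and in the camera test for antimicrobial peptides and recognition proteins (adjusted p = 8.87e-04, and 0.133 with an estimated correlation). Probes with no single gene name, which no comparison used, also carried a signal: 318 of 2492 differed between the species, 136 higher and 182 lower in sechellia and 78 by more than 2-fold, a share of 12.8% against 16% of the named probes.

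In the Test over Ref ratio, between-species arrays of opposite labelling ran in opposite directions. If Test held sechellia on all of these arrays, as the columns of the value table have it, both sets would run the same way, which their correlation of -0.509 argues against. If Test was 1 dye throughout, the part common to both sets would be a dye effect, and its correlation of 0.744 with the arrays that hold a single species goes with that. If Test was Cy5, genes fitted as higher in sechellia would be dimmer on the sechellia-only than on the simulans-only arrays, and the correlation of 0.882 over 411 genes argues against it. On those arrays Def had a mean log2 intensity of 14.5 in sechellia and 10.5 in simulans, and Obp56e 13.0 and 15.1.

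Of the 10 genes past the threshold for choice in sechellia, 8 moved towards the simulans level, and chance in the directions of so few genes cannot be told apart from a pattern (p = 0.109, exact 2-sided sign test). For compressed ratios on some between-species arrays, the 2 arrays that hold only sechellia cannot decide. There the choice ratio correlated with the species difference at -0.294 (array 2) and -0.441 (array 7) over 102 bright genes that differ by more than 2-fold. However, the Test channel had its narrowest range on arrays 3, 6 and 7, where it held sechellia choice samples. Its log2 range without the extreme spots was 2.29, 2.26 and 2.50 there, against 2.68 to 4.29 elsewhere. Array 7 may thus be compressed itself, and array 2 is a single array, the one with the lowest net signal in both channels. Simulans RNA mixed into the sechellia choice samples would need a fraction of 7.15% for Obp56e and CG11426, which predicts a median rise of 0.48 for the other 47 genes at least 4-fold lower in sechellia under no choice. Their median was -0.20 ± 0.13 (SE), with 17 of them over 3 SE below the prediction, and that of the 34 brighter than the median gene -0.14 ± 0.16 against 0.48 predicted, which argues against it, while the 36 lower genes among the 102, at -0.05 with 0.16 predicted, do not decide. Arrays 3, 6 and 7 all belong to series A, and all 10 genes kept the sign of their choice effect in either series alone. Because the genes were called on both series together, this does not decide on compression. A response of the 10 genes to the choice treatment stays open, as do chance and compressed ratios. Only 58 of the 102 genes (56.9%) moved that way, and in simulans 61.8% moved towards sechellia, with r = 0.290 (0.230 and 0.0695 on the simulans-only arrays).

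Of 10 measured genes of plasmatocytes and crystal cells, 5 were lower in sechellia and 0 higher, and the rest did not pass. A different share of haemocytes in the heads would move every well measured marker, and apart from PPO1 and PPO2, which led to the list, only 2 markers were brighter than the median gene, both lower in sechellia, too few to decide. That cut was set after the data were seen. Among the dimmer markers NimC1 was lower (-1.22 ± 0.18) and the others did not pass. The crystal cell markers lz (0.06 ± 0.22) and peb (-0.30 ± 0.20) thus did not move with PPO1 and PPO2, but dim genes cannot decide. Probe sequences that match simulans better cannot be told apart from a different share of haemocytes, because 0 further probes of the 4 brighter genes had a value. Expression per cell that differs between the species was not tested.

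The counts of genes were set against 100 splits of the labelled samples, with species labels exchanged within a treatment and dye, and choice labels within a species and dye. Apart from the single gene of simulans, which other splits equalled, no other split reached a real count. With 100 splits, 1 in 100 is the smallest share that could be found. Exchanged species labels also put the species difference into the spread, which lowers the counts of those splits. Chance in the spread between labelled samples, which may be technical, is thus made less likely but not excluded. The splits say nothing of flies or cages, and the limma count for choice in sechellia is 0 without array 7 (516 at unadjusted p) and that for the interaction 0 without array 3 or 7 (576 and 537). As many genes as the real 1756 for the species were found in 1 split, the real one, with a highest other of 1. Under no choice 1 split reached 918 (highest other 13) and under choice 1 reached 1018 (highest other 3). For choice in sechellia 1 split reached 10 (highest other 0), for choice in simulans 3 reached 1 (highest other 1), and for the interaction 1 reached 3 (highest other 1).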

How the results depend on the processing

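The brighter genes alone, the value table with its own columns and each slide series alone were settings chosen only after the results had been seen; the other settings were planned. In every setting run for single genes, which leaves out the value table with its own columns, the named genes past a threshold kept their direction. Of the 78 such genes for the species, 62 passed in each planned setting other than averaged swaps and direct arrays, against 0 of 10 for choice in sechellia, 0 of 1 in simulans and 0 of 3 for the interaction. Counts are given for species, species under no choice, species under choice, choice in sechellia, choice in simulans and interaction, which were 1756, 918, 1018, 10, 1 and 3; a result left out of a setting stayed within 1.5 times. Averaged dye swaps gave 649, 142, 143, 0, 0 and 0 in limma (562, 684 and 626 at unadjusted p for the last 3). Direct arrays gave 21, 3, 49, 0, 0 and 0 (347, 443 and 507). Fewer residual degrees of freedom are part of both settings and of either slide series alone, so their low counts do not show a failure to repeat. Series A alone gave 333, 0, 22, 0, 0 and 0 and series B alone 0 for all 6, with 1233, 723, 896 and 762 at unadjusted p for the zeros of A and 1362, 1492, 759, 410, 647 and 281 for B. The value table's own columns gave 0 for all but the species count (2456, 2624, 1226, 627 and 237 at unadjusted p), which was 2370, of which 386 were shared and 201 of these had the same direction. For choice in sechellia the count was 30 without background correction, 36 with subtraction, 23 with print-tip loess, 4 with the slide series as a block, 25 with array weights, 315 in the value table, 28 in the separate-channel fit, 16 with the replicate block and 42 over the brighter 5077 genes. For choice in simulans it was 2 with subtraction, 0 with an offset of 0, 3 with print-tip loess, 0 with the slide block, 0 with array weights (760, 817 and 652 at unadjusted p for the zeros), 7 in the separate-channel fit and 6 with the replicate block. For the interaction it was 10 without background correction, 13 with subtraction, 1 with an offset of 0, 14 with print-tip loess, 0 with median centring (588 at unadjusted p), 1 with the slide block, 8 with array weights, 9 in the value table, 17 in the separate-channel fit, 10 with the replicate block and 15 over the brighter genes. Array weights gave 1969 for the species under choice. With each array left out in turn the counts ran from 1312 to 1867, 578 to 933, 451 to 1023, 0 to 12, 0 to 1 and 0 to 2. The arrays that moved a count by more than 1.5 times were array 8 under no choice (578), arrays 3 and 10 under choice (451 and 460), arrays 2, 3, 7, 10 and 11 for choice in sechellia (1, 3, 0, 4 and 2), arrays 1, 5, 9, 10 and 11 for choice in simulans (0) and, for the interaction, arrays 3 and 7 (0) and all others but array 4 (1). Of 28 lists, camera called 3 for the species, 1 for choice in sechellia, 0 in simulans and 1 for the interaction; an estimated correlation gave 0 in all 4, fry 17, 2, 0 and 1, and median centring 3, 2, 0 and 2. Of the genes fixed in advance other than Obp56e, none of them past the threshold, Osi8 turned to -0.0331 without background correction and -0.515 in series A, Osi6 to 0.0016 in the value table, and Obp57e to 0.0063 with subtraction, 0.0505 with print-tip loess, 0.0202 in the value table and 0.42 in series B, with -0.34 to 0.0185 over arrays left out. Or85b turned to -0.0074 without background correction, -0.0272 with print-tip loess, -0.0174 in the value table and -0.12 in series A, with -0.0684 to 0.23 over arrays left out. Except where fewer arrays enter, the cause was not tested. No pairing by the numbers in the sample titles was seen. Over 64 pairs of samples of different groups with the same number r ran from -0.31 to 0.30 with a median of 0.00, against a median of -0.02 over 140 pairs with other numbers. Samples of the same group and number in the other dye also had a median of only 0.008 (12 pairs), so the check could miss a pairing. Signal limits the counts: of 4 classes of brightness, 4.77% of the genes in the dimmest differed between the species and 39.9% in the brightest, where 9 of the 10 choice genes of sechellia lie, with a median SE of 0.26 and 0.11. Both background filters removed no gene and say nothing about stability.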

Other observations

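The marker list for blood cells and the basement membrane genes below were chosen, and the list tested, only after PPO1 and PPO2 had been seen among the genes with the largest species differences.

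Of 10 measured plasmatocyte and crystal cell genes, 5 were lower in sechellia heads and 0 higher: the crystal cell prophenoloxidases PPO2 (-3.47 ± 0.23) and PPO1 (-3.41 ± 0.39), and in plasmatocytes the phagocytosis receptor gene eater (-2.69 ± 0.38), the clotting protein gene Hml (-2.47 ± 0.14) and NimC1 (-1.22 ± 0.18). Nplp2 (-0.86), peb (-0.30), Pxn (-0.24), Sr-CI (-0.18) and lz (0.06) did not pass. Since PPO1 and PPO2 led to the list, they were left out of its test: of the other 8 genes 3 were lower, and over the 6 of them with values on all arrays camera gave p = 0.0037, and p = 0.0177 with an estimated correlation. Lamellocyte genes, which mark the blood cells formed after wasp attack, ran both ways, with PPO3 (0.77) and atilla (0.55) higher, mys (-0.76) lower and ItgaPS4 (0.46) not past the threshold.

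Of 8 basement membrane genes, also looked up afterwards and not tested as a list, 5 were lower: the collagen gene Col4a1 by 2.38-fold (-1.25 ± 0.10), Ppn (-1.65 ± 0.15), LanA (-0.71), LanB2 (-0.55) and SPARC (-0.45). The second collagen gene vkg (-0.73, adjusted p = 0.0614), Pxn and LanB1 (0.22) did not pass. None of these genes passed for choice in sechellia, where Col4a1 changed by 0.27 (adjusted p = 0.754), Hml by 0.08 (adjusted p = 0.962) and PPO2 by -0.71 (adjusted p = 0.713).

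Over genes whose brightest probe passed for the species effect, 168 of 235 other probes had the same sign (71.5%), with r = 0.637.

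The choice effects of the species correlated little across genes, with r = -0.06 over all 10155 genes and -0.0048 over the brightest 1270. Simulated data with noise and dye effects but no change gave -0.0088 and -0.03. The choice effect in sechellia had a median SE of 0.29 against an SD over genes of 0.40. Noise therefore weakens r, and unrelated responses are not shown. The species difference and the choice effect in sechellia correlated at 0.10 over all genes and -0.14 over the brightest, against 0.0031 and -0.02 in the simulated data.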
